A study of Mus musculus with 112 samples.

How the data were processed

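The deposited table holds log10 ratios of 32640 probe sets on 112 arrays. Per the labels, the authors processed the arrays with Rosetta Resolver and expressed each array relative to a virtual pool of the HFD Pro/Pro group. The labels name an Affymetrix mouse array and nominal dye channels. In fat and liver the base, direction and pool were settled from the values. Over the 10 HFD Pro/Pro arrays of fat, and of liver, the mean of 10 to the power of the deposited log10 ratio was 1 within 0.001 on the log10 scale for 100% of probe sets, while, over the 500 most variable probe sets, ratios taken the other way were off by a median of 0.2 in fat and 0.0816 in liver. In muscle 8 of the 10 pool arrays were analysed here, so this check could not be completed. There the mean over those 8 was off by a median of 0.0224 on the log10 scale with base 10, by 0.0232 with base 2 and by 0.0516 with ratios taken the other way, and 10.54% of probe sets lay within 0.001, so base, direction and pool were taken from the other tissues and the deposited table's labels. The sample descriptions name a pool of RNA from 10 wild-type samples, unlike the series text and titles. Array medians lay between -0.0658 and 0.0262 on the log2 scale. The table has a floor of -2, a ratio 100 times below the pool, reached by 64 values (62 in fat, 2 in muscle, 0 in liver). No intensities were used here, so signal over background is unknown, and the authors' filter on expressed genes could not be applied. Pairwise correlations between arrays went down to -0.469 in fat, -0.204 in muscle and -0.387 in liver. In fat and liver the direction is fixed by the pool arithmetic.

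Of the probe sets 25508 have 1 gene symbol, 0 have several and 7132 have none. Symbols were brought up to date with an NCBI gene table of GRCm38.p6. Of the symbols 21388 were current, 4066 were matched through a synonym and 54 were kept as given. This table was used only for names and gene order. A gene was represented by the probe set with the highest variance within tissues, blind to the groups, which gave 16643 genes. Ratios were turned to log2. Groups and mouse numbers come from the labels. Replicates are separately numbered mice. Of 41 mice 31 were measured in 3 tissues, 9 in 2 and 1 in 1.

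For each tissue limma 3.58.1 in R 4.3.3 fitted 1 mean per group, with contrasts for genotype on each diet and on both, diet in each genotype and their interaction, at an adjusted p of 0.05. Differences between tissues were fitted over all 12 groups, without and with mouse number as a block. The numbers mark the same animal per the labels. As a check, deviations from group means over all genes correlated between same-numbered arrays with a median of 0.0273 for fat and muscle, -0.00523 for fat and liver and -0.00379 for muscle and liver. Gene lists (30, fixed before the data were examined, as were the fits and the alternatives not named below as added) were tested with camera at a preset correlation of 0.01. An additional hepatocyte list was completed after the data were seen. The genes named are Pparg in each genotype contrast, the up to 6 largest rises and falls past the threshold, without clone and model symbols unless fewer than 5 genes remained, the 5 smallest p where fewer than 5 passed, and up to 4 members of each list with the smallest p in a contrast. The text names part of the genes the rule gives, and this part was picked after their values were seen.

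The fit was tested on simulated data with 200 changed genes of 16643. For the genotype comparison under HFD it recovered 85% of changes of 0.5 and 96% of changes of 1 (log2) in fat, 95% and 99% in muscle, and 87% and 99% in liver. False calls were 8 of 189 in fat, 16 of 210 in muscle and 10 of 196 in liver. The simulated genes were independent of each other, unlike real genes. With 200 changed genes the adjusted threshold is easier to pass, so recovery would be lower where fewer genes change. Alternatives were median centring, quantile normalization, averaging or testing all probe sets, genes above the median variance, array weights, mouse number as a covariate, leaving out each mouse, the authors' false discovery rate of 0.20, and the methods' t-test, which the series text names for the genotype comparison. Alternatives added after seeing the data were the first component of the residuals as a covariate, fat without 10 arrays with transcripts of other organs, the adipocyte list as a covariate in muscle, the whole chromosome as the window around Pparg, and list tests without each array in turn.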

Results

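RNA from 3 tissues of male mice was measured on 112 microarrays. Per the sample titles these were epididymal white fat (eWAT), gastrocnemius muscle (Gastroc) and liver, called fat, muscle and liver below. The mice carried the Pro12Ala variant of Pparγ, the nuclear receptor that drives adipocyte differentiation, on both chromosomes (Ala/Ala) or were wild-type littermates (Pro/Pro). They ate rodent chow or a high-fat diet (HFD) from an age of 8 weeks. The labels give 15 weeks of diet in the series text and 12 weeks in the sample descriptions, and they also name different feeds. In fat there were 10 Pro/Pro chow, 10 Pro/Pro HFD, 9 Ala/Ala chow and 8 Ala/Ala HFD arrays. In muscle there were 8, 8, 10 and 9 arrays in the order Pro/Pro chow, Pro/Pro HFD, Ala/Ala chow and Ala/Ala HFD. In liver there were 10 in each group. The arrays came from 41 numbered mice. Per the sample titles every value is a ratio of a mouse to a virtual pool of the HFD Pro/Pro group of its tissue, given here as log2, while the sample descriptions name a pool of RNA from 10 wild-type samples. The values fit the mean of the HFD Pro/Pro arrays in fat and liver. In muscle the pool, the log base and the direction could not be settled from the values and were taken to be the same, so the size and sign of muscle differences rest on this. Expression levels cannot be read from a ratio, and the number of arrays limits the precision. Errors below are standard errors of limma's fitted differences unless an SD is named. Adjusted p-values of genes are limma's after Benjamini-Hochberg adjustment over 16643 genes. Those of gene lists are camera's, adjusted only over the lists tested in that contrast and tissue. Members adjusted over the list alone were adjusted over the measured genes of that list.

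The first question was whether the variant changed gene expression in fat. Over both diets 9 genes differed between genotypes, 3 higher and 6 lower in Ala/Ala. Slc6a13, a transporter of GABA and taurine, fell by 0.84 ± 0.09 on the log2 scale (adjusted p = 1.04e-06). Bid, a pro-apoptotic member of the Bcl-2 family, fell by 0.55 ± 0.06 (adjusted p = 2.95e-06). Dtna, a component of the dystrophin complex, fell by 0.53 ± 0.09, Tmcc1 by 0.42 ± 0.08, Bcl2l13, a mitochondrial Bcl-2 relative, by 0.36 ± 0.05 and Ddo, which oxidises D-aspartate, by 0.32 ± 0.06. Apobec1, the cytidine deaminase that edits apolipoprotein B mRNA, rose by 0.69 ± 0.12, Klra17 by 0.54 ± 0.11 and Hdhd5 by 0.26 ± 0.04. Pparg itself differed by -0.04 ± 0.08 (adjusted p = 0.944), which did not pass. The calls of Dtna, Tmcc1, Bcl2l13, Ddo and Klra17 ended when all probe sets of a gene were averaged, and those of Tmcc1, Ddo and Klra17 after quantile normalization. For Bcl2l13 the other probe sets differed in the opposite direction, by 0.17 and 0.18.

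Under chow 3 genes differed in fat, all lower in Ala/Ala. They were Slc6a13 (-0.78 ± 0.13), Bid (-0.58 ± 0.09) and Bcl2l13 (-0.40 ± 0.07), and Pparg differed by -0.11 ± 0.12 (adjusted p = 1). None of these 3 passed after quantile normalization. Under HFD 17 genes differed, 2 higher and 15 lower. Slc6a13 fell by 0.91 ± 0.13, Dtna by 0.67 ± 0.13, Nfic, a transcription factor, by 0.52 ± 0.10 and Kdm5a, a histone demethylase, by 0.49 ± 0.10, while Apobec1 rose by 0.88 ± 0.18. Pparg differed by 0.03 ± 0.12 (adjusted p = 0.959). The calls of Dtna, Nfic, Kdm5a and Apobec1 ended when probe sets were averaged. After quantile normalization 4 of 11 calls were higher, against 2 of 17. The HFD count rested on single arrays, since 11 of 18 single omissions moved it by over 1.5 times, down to 3 without Mouse110, Mouse111 or Mouse149, and the methods' t-test called 2 genes. It was 1 without the 10 fat arrays that held transcripts of other organs, an alternative chosen after seeing the data. All of these but Mouse73 and Mouse113 were HFD arrays. The smaller number of arrays and the removal of those transcripts were not told apart. No gene passed the test of the difference between the diets in the genotype effect, limma calling 0 genes with 731 at an unadjusted p under 0.05, and 1 gene with mouse number as a covariate.

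No member of the fixed gene lists differed by genotype in fat, so the lists are given by their set tests. None of these calls held with an estimated correlation, where the adjusted p was 0.565 for each on chow, 0.776 on HFD and 0.907 for each over both diets. The adipocyte PPARγ target list lay higher in Ala/Ala on chow, by a mean of 0.05 over 24 measured members (camera adjusted p = 0.008). This call ended without Mouse74 (0.04), Mouse114 (0.03) or Mouse120 (0.03), and the mean was 0.08 without Mouse113. The list did not pass on HFD (0.02, adjusted p = 0.792) or over both diets (0.04, adjusted p = 0.148). The insulin signalling list was 0.06 higher on chow (adjusted p = 0.0464), a call that ended in 13 of 19 single omissions and when probe sets were averaged. The extracellular matrix list was 0.12 higher on HFD (adjusted p = 0.029) and 0.06 higher over both diets (adjusted p = 0.0207), calls that 6 of 18 and 10 of 37 single omissions ended, with means of 0.06 and 0.03 without Mouse152. The cholesterol synthesis list lay lower in Ala/Ala, with a mean difference of -0.10 over 19 measured members over both diets (adjusted p = 0.000864) and -0.11 on chow (adjusted p = 0.00217), and 0 members passed, also when adjusted over the list alone. The means were -0.07 without Mouse77 and -0.07 without Mouse105. The lipogenesis list differed by -0.12 on chow (adjusted p = 0.008) and -0.09 over both diets (adjusted p = 0.015), calls that 7 of 19 and 4 of 37 single omissions ended, with chow means of -0.08 without Mouse109, -0.07 without Mouse91 and -0.07 without Mouse113. The interferon response list lay lower on chow, by a mean of -0.13 over 16 members (adjusted p = 1.39e-05), and over both diets, by -0.07 (adjusted p = 0.0166). The chow call rested on a single Pro/Pro array, Mouse106, without which the means were -0.04 (adjusted p = 0.116) and -0.03 (adjusted p = 0.238), and the call over both diets also ended without Mouse110, Mouse113 or Mouse149 (each -0.06).

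Lists of other cell types and of sample quality differed beside these, and their calls were also lost with an estimated correlation (adjusted p = 0.565 for each on chow and 0.907 over both diets). The mesothelium list differed by -0.24 on chow (adjusted p = 0.008) and -0.26 over both diets (adjusted p = 0.0136). Its chow call ended without Mouse114 (-0.14) or Mouse120 (-0.17) and the other without Mouse117 (-0.19). The lymphocyte list differed by -0.12 on chow (adjusted p = 0.008), and by -0.08 without Mouse72, which was not called. The immediate early genes, fixed as a sign of sample quality, were 0.10 higher on chow (adjusted p = 0.0123), a call that ended without Mouse74 (0.09), Mouse105 (0.07), Mouse109 (0.04) or Mouse120 (0.05).

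The second question was the response of fat to the diet, which was broad. In Pro/Pro mice 1940 genes were higher and 2051 lower on HFD, and in Ala/Ala mice 2444 were higher and 2120 lower. Ncan, a brain proteoglycan, rose by 2.66 ± 0.25 in Pro/Pro and 2.67 ± 0.27 in Ala/Ala. Pla2g2e, a secreted phospholipase, rose by 2.50 ± 0.18 and 2.49 ± 0.20, and the stearoyl-CoA desaturase gene Scd2 by 2.21 ± 0.25 and 2.49 ± 0.28. Cyp1a1, a target of the aryl hydrocarbon receptor, rose by 2.63 ± 0.46 and 2.44 ± 0.50. Mmp9, a gelatinase, fell by 1.90 ± 0.11 and 1.87 ± 0.12 and Dennd2d fell by 1.46 ± 0.17 and 1.60 ± 0.18. Other large changes, which passed in both genotypes, are given for the genotype that ranked them. In Pro/Pro Tfr2 rose by 2.28 ± 0.37 and Lipf by 2.15 ± 0.24, Hsd11b1, which regenerates corticosterone, fell by 1.42 ± 0.14 and St6galnac5 fell by 1.66 ± 0.31. In Ala/Ala Fgf13 rose by 2.44 ± 0.33 and Inmt fell by 1.87 ± 0.26.

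The cholesterol synthesis list rose together in fat on HFD. Of 19 measured members 16 rose and 0 fell in each genotype, and adjusted over the list alone 16 rose in Pro/Pro and 17 in Ala/Ala. Lanosterol synthase Lss rose by 1.37 ± 0.15 in Pro/Pro and 1.45 ± 0.16 in Ala/Ala, and Nsdhl by 0.921 ± 0.126 and 0.995 ± 0.137. The SREBP regulator Insig1 rose by 1.29 ± 0.18 and Hsd17b7 by 0.85 ± 0.10 in Pro/Pro, and Tm7sf2 by 1.22 ± 0.17 in Ala/Ala. The set test gave adjusted p of 4.47e-13 and 2.65e-10, and 0.272 and 0.275 with an estimated correlation. Mean list levels were -0.75 ± 0.25 (SD, n = 10) on chow and -0.03 ± 0.22 (SD, n = 10) on HFD in Pro/Pro, and -0.86 ± 0.18 (SD, n = 9) and -0.12 ± 0.26 (SD, n = 8) in Ala/Ala.

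**Figure D1:**
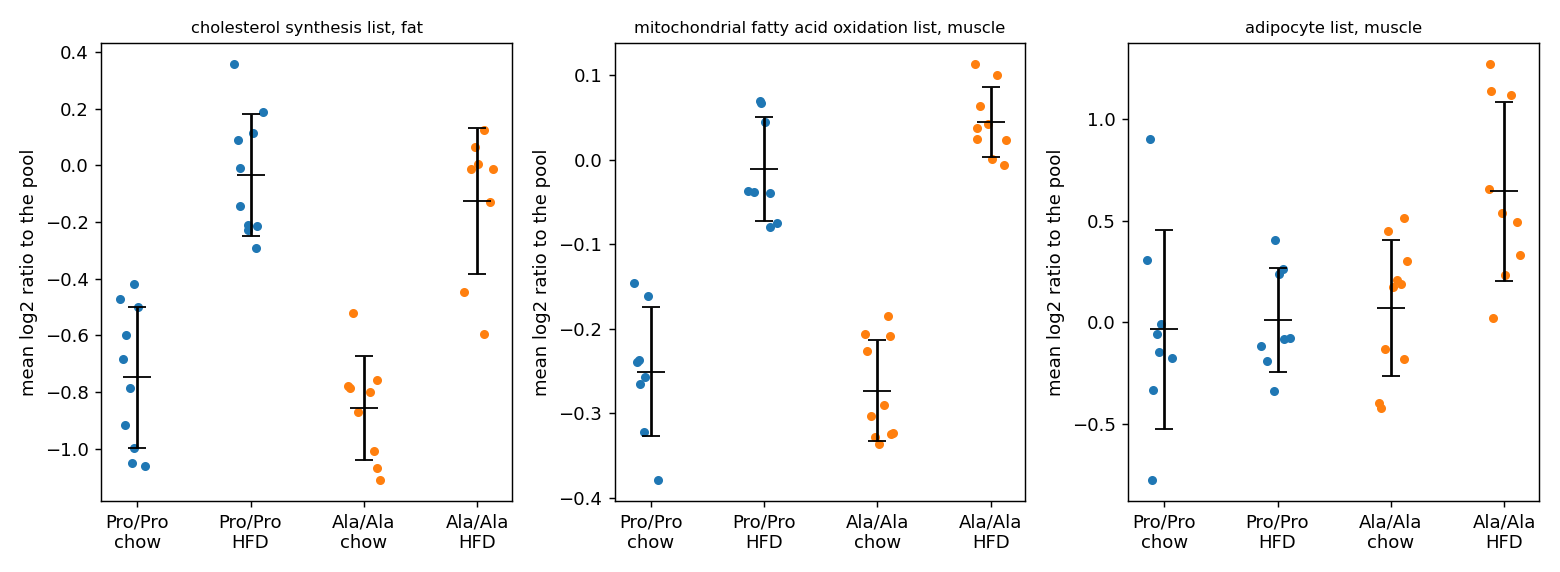
Mean log2 ratio to the pool (vertical axis) of the cholesterol synthesis list in fat, and of the mitochondrial fatty acid oxidation and adipocyte lists in muscle, for each array (points) in the 4 groups, with the mean and SD (bars). All 9 Ala/Ala HFD muscle arrays lay between 0.02 and 1.27 on the adipocyte list, and the 8 Pro/Pro HFD arrays between -0.34 and 0.40.

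Other lists in fat moved in mixed ways. Of 19 insulin signalling members 1 rose and 5 fell in Pro/Pro, and 1 rose and 8 fell in Ala/Ala (set test adjusted p = 0.0476 and 0.00132, and 0.357 and 0.0754 with an estimated correlation), and the Pro/Pro call ended in 11 of 20 single omissions. The insulin receptor gene Insr fell by 0.50 ± 0.07 in Pro/Pro and 0.57 ± 0.08 in Ala/Ala, Grb10 by 0.35 ± 0.05 in Pro/Pro and Pik3r1 by 0.78 ± 0.15 in Ala/Ala. Of 10 adipokines 5 rose and 4 fell in each genotype. Leptin (Lep) rose by 1.69 ± 0.20 and 1.45 ± 0.22 and chemerin (Rarres2) by 0.66 ± 0.07 and 0.70 ± 0.07, while adipsin (Cfd) fell by 0.39 ± 0.05 and 0.44 ± 0.06 and angiotensinogen (Agt) by 1.10 ± 0.13 and 1.40 ± 0.14. The lipogenic regulator Mlxipl fell by 0.97 ± 0.13 and 1.08 ± 0.14, and Acss2, which makes acetyl-CoA, rose by 1.12 ± 0.22 and 1.39 ± 0.23. Of 16 circadian clock genes 0 rose and 4 fell in Pro/Pro and 5 fell in Ala/Ala, where the set test gave an adjusted p of 0.0235 (0.289 with an estimated correlation) and did not pass without Mouse152. Per3, Nr1d2 and Clock fell by 0.69 ± 0.16, 0.71 ± 0.18 and 0.37 ± 0.10 in Pro/Pro and by 0.78 ± 0.17, 0.66 ± 0.19 and 0.44 ± 0.11 in Ala/Ala.

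Genes of other cell types also differed with diet in fat. Of 18 macrophage markers 4 rose and 4 fell in Pro/Pro and 5 rose and 1 fell in Ala/Ala, and their set test did not pass (adjusted p = 0.965 and 0.342). Itgax, Lgals3 and Mmp12 rose by 0.75 ± 0.22, 0.68 ± 0.15 and 1.62 ± 0.46 in Pro/Pro and by 1.10 ± 0.24, 0.80 ± 0.16 and 1.97 ± 0.50 in Ala/Ala, while Cd14 fell by 0.66 ± 0.11 and 0.68 ± 0.12. The call of Itgax in Pro/Pro ended after quantile normalization. Of 8 mesothelial markers 4 fell in each genotype (set test adjusted p = 0.0468 and 0.0516, and 0.78 and 0.834 with an estimated correlation), and the Pro/Pro call ended in 4 of 20 single omissions. Wt1 fell by 0.82 ± 0.12 and 0.80 ± 0.12, and Upk3b by 0.83 ± 0.18 in Pro/Pro. Of 14 brown and beige adipocyte genes 4 rose and 1 fell in Pro/Pro and 6 rose and 2 fell in Ala/Ala, and the set test did not pass (adjusted p = 0.425 and 0.176). Cox7a1 rose by 1.21 ± 0.19 and 1.29 ± 0.20 and Otop1 by 1.43 ± 0.33 and 2.33 ± 0.36, and Ppargc1b fell by 0.66 ± 0.13 and 0.79 ± 0.14. The mean of the epididymis and testis list was -2.46 ± 0.15 (SD, n = 10) in Pro/Pro chow and -1.64 ± 1.14 (SD, n = 10) in Pro/Pro HFD, where single arrays reached 0.86. A hepatocyte list completed after seeing the data ranged from -3.51 to 2.84 over the fat arrays, and 0 of its 8 measured members differed by diet or genotype. In Ala/Ala the epididymis and testis list averaged -2.48 ± 0.09 (SD, n = 9) on chow and -1.84 ± 0.88 (SD, n = 8) on HFD. Hepatocyte list means on chow and HFD were -2.44 and -1.48 in Pro/Pro (SD 1.6 and 1.91) and -2.21 and -1.05 in Ala/Ala (SD 2.04 and 2.02). Without the 10 arrays high in either list, all but Mouse73 and Mouse113 on HFD, the Ala/Ala diet count was 2962. Fewer arrays were then compared, so a change in count was not tied to these transcripts.

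The diet response of fat overlapped between genotypes. Of the genes higher on HFD 1438 were shared, against 285 for independent lists, and of those lower 1530 were shared, against 261. No array was in both comparisons. The spread of each gene was estimated from all groups of the tissue together, so the lists are not fully independent. Whether the response differed was tested by the diet-by-genotype term given above, which called 0 genes.

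In muscle, 6 genes differed between genotypes over both diets. Hdhd5 rose by 0.44 ± 0.05 (adjusted p = 1.19e-06), the zinc finger gene Zfp9 by 0.45 ± 0.05, Retnla, a resistin-like secreted protein, by 0.45 ± 0.07 and Erc1 by 0.23 ± 0.03, Bcl2l13 fell by 0.16 ± 0.03 and the other call was a clone symbol. The count was 11 without Mouse84 and 10 without Mouse127. Pparg differed by 0.17 ± 0.08 (adjusted p = 0.661). The direction of Bcl2l13 turned when its probe sets were averaged, to 0.00422 (adjusted p = 0.983). Under chow Hdhd5, Zfp9 and Erc1 rose by 0.44 ± 0.07, 0.47 ± 0.07 and 0.25 ± 0.05, and Bcl2l13 and 3110021A11Rik fell by 0.20 ± 0.04 and 0.27 ± 0.05. After quantile normalization 3 of 4 chow calls were higher, against 3 of 5, and the chow call of Bcl2l13 ended, as did that of Erc1 when probe sets were averaged. The chow count was 2 without Mouse73, 3 without Mouse101 or Mouse106 and 0 by the methods' t-test. Under HFD Hdhd5 and Zfp9 rose by 0.44 ± 0.07 and 0.42 ± 0.08. Zfp9 did not pass there after quantile normalization, and this count ran from 1 to 6 when single mice were left out. Retnla there was 0.51 ± 0.10 higher (adjusted p = 0.0636) and Pparg 0.31 ± 0.11 higher (adjusted p = 0.446), neither of which passed. Retnla passed when probe sets were averaged. Under chow Pparg differed by 0.03 ± 0.11 (adjusted p = 1). The interaction of diet and genotype called 0 genes in limma, with 652 at an unadjusted p under 0.05.

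The list of adipocyte markers was higher on average in Ala/Ala than in Pro/Pro muscle under HFD. The adipocyte list averaged 0.64 ± 0.44 (SD, n = 9) in Ala/Ala HFD and 0.01 ± 0.26 (SD, n = 8) in Pro/Pro HFD. All 6 of its measured members are also in other lists. Over all genes 0 of them passed, adjusted over the list alone 5 rose, and the set test gave an adjusted p of 3.2e-06 (0.21 with an estimated correlation). Beside it the PPARα target list lay 0.22 higher (adjusted p = 0.000536, and 0.444 with an estimated correlation), with 0 of 17 members passing over all genes and 4 adjusted over the list alone. With the adipocyte list as a covariate, chosen after seeing the data, the HFD genotype count was 0 and the PPARα target list lay 0.11 higher, which did not pass (adjusted p = 0.11). Lists of unfolded protein response (0.08, adjusted p = 0.00113), fatty acid oxidation (0.06, adjusted p = 0.00125), slow myofibre (0.20, adjusted p = 0.0132), oxidative phosphorylation (0.03, adjusted p = 0.0298) and extracellular matrix genes (0.07, adjusted p = 0.0339) were also called higher on HFD, and none of them with an estimated correlation (adjusted p = 0.444 for the first 2 and 0.525 for the others). Slow myofibre was 0.08 without Mouse125 and 0.16 without Mouse80 or Mouse152, none called, and 0.40 with the covariate. Of 17 single omissions 5 ended the call of oxidative phosphorylation and 5 that of extracellular matrix, which was 0.04 without Mouse152 and -0.02 with the covariate (adjusted p = 0.817). The unfolded protein response list was also called on chow (0.06, adjusted p = 0.00636, and 0.891 with an estimated correlation), where the call ended without Mouse105, Mouse109 or Mouse114 (each 0.05), and over both diets (0.07, adjusted p = 3.68e-05, and 0.304 with an estimated correlation). Over both diets the adipocyte list was 0.37 higher (adjusted p = 0.000142, and 0.304 with an estimated correlation), the PPARα target list 0.10 (adjusted p = 0.0128, and 0.531 with an estimated correlation) and the extracellular matrix list 0.06 (adjusted p = 0.00418, and 0.54 with an estimated correlation). The PPARα call there ended without Mouse105 (0.07), Mouse143 (0.08) or Mouse155 (0.09), and with the covariate (0.03, adjusted p = 0.395), and the extracellular matrix call without Mouse109 (0.04) and with the covariate (0.01, adjusted p = 0.696).

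Genes of mitochondrial fatty acid oxidation were higher on HFD than on chow in muscle. Of 20 measured list members 14 rose in Pro/Pro and 16 in Ala/Ala and 0 fell, and adjusted over the list alone 17 and 18 rose. The set test gave adjusted p of 1.08e-33 and 5.01e-54, and 0.000451 and 9.82e-06 with an estimated correlation. The acyl-CoA dehydrogenase genes Acadvl and Acadl rose by 0.34 ± 0.04 and 0.42 ± 0.05 in Pro/Pro and by 0.42 ± 0.03 and 0.50 ± 0.05 in Ala/Ala. The thiolase Acaa2 rose by 0.43 ± 0.05 and 0.54 ± 0.05, the carnitine carrier Slc25a20 by 0.42 ± 0.05 and 0.45 ± 0.04, and Etfdh by 0.39 ± 0.04 in Ala/Ala. Beside it the adipocyte list was 0.575 higher on HFD in Ala/Ala. Mean list levels were -0.25 ± 0.08 (SD, n = 8) and -0.01 ± 0.06 (SD, n = 8) on chow and HFD in Pro/Pro, and -0.27 ± 0.06 (SD, n = 10) and 0.04 ± 0.04 (SD, n = 9) in Ala/Ala.

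Across muscle as a whole 120 genes rose and 175 fell on HFD in Pro/Pro, and 231 rose and 226 fell in Ala/Ala. Cyp1a1 rose by 1.37 ± 0.28 and 1.82 ± 0.26, the desaturase Scd1 by 1.13 ± 0.31 and 1.84 ± 0.28 and the natriuretic peptide clearance receptor Npr3 by 0.93 ± 0.21 and 1.52 ± 0.19. Scd2 and the acetylcholine receptor subunit Chrna2 rose by 1.03 ± 0.18 and 0.97 ± 0.14 in Pro/Pro. Cardiac actin (Actc1) fell by 1.07 ± 0.17 and 0.82 ± 0.15, Plet1os by 0.85 ± 0.13 and 0.78 ± 0.12, Frmd7 by 0.82 ± 0.15 in Pro/Pro and Kera by 0.78 ± 0.14 in Ala/Ala. The glucose transporter Slc2a4 fell by 0.18 ± 0.04 and 0.15 ± 0.04, Tbc1d1 rose by 0.37 ± 0.08 and 0.28 ± 0.07 and myoglobin (Mb) by 0.15 ± 0.03 and 0.18 ± 0.03. Of 17 PPARα targets 2 rose in Pro/Pro and 6 in Ala/Ala (set test adjusted p = 0.0232 and 4.28e-09, and 0.715 and 0.04 with an estimated correlation). The Pro/Pro list mean of 0.05 turned to -0.00643 without Mouse105, and the Ala/Ala mean of 0.30 was 0.20 with the adipocyte list as a covariate (adjusted p = 0.283 with an estimated correlation). Among the genes that rose were Cpt1b by 0.26 ± 0.05 and 0.25 ± 0.04, and in Ala/Ala Cd36 by 0.46 ± 0.07 and Acot1 by 0.89 ± 0.17. Of the 6 adipocyte markers 1, Lep, rose in Ala/Ala, by 1.71 ± 0.27 (list set test adjusted p = 0.000166, and 0.208 with an estimated correlation). The oxidative phosphorylation list was 0.02 higher in Pro/Pro (adjusted p = 0.0156, and 0.715 with an estimated correlation) and 0.06 in Ala/Ala (adjusted p = 5.05e-07, and 0.208 with an estimated correlation), and 4 of 16 omissions ended the Pro/Pro call, to 0.01 without Mouse84 or Mouse123. Interferon response was 0.10 higher in Pro/Pro (adjusted p = 0.0416, and 0.715 with an estimated correlation), a call that 8 of 16 omissions and the adipocyte covariate ended. Slow myofibre genes were 0.15 higher in Ala/Ala (adjusted p = 0.00868, and 0.529 with an estimated correlation), 0.09 and not called without Mouse121, and 0.33 with the covariate. The calls of Scd1 and Slc2a4 in Pro/Pro ended with mouse number as a covariate, and Slc2a4 did not pass after quantile normalization in either genotype. The Pro/Pro count was 189 after quantile normalization, 139 by the methods' t-test and 193 without Mouse147 or Mouse94. Between genotypes 75 rising genes were shared, against 1.67 for independent lists, and 81 falling genes, against 2.38. As in fat, both comparisons used the same estimate of each gene's spread.

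In liver the groups are those of the labels, and the arrays did not match the same-numbered fat and muscle arrays, as given further on, so each liver direction holds for arrays labelled with that genotype or diet. No gene differed between arrays labelled HFD and chow in either genotype. Limma called 0 genes in Pro/Pro with 992 (5.96% of genes) at an unadjusted p under 0.05, and 0 in Ala/Ala with 471 (2.83%). A share of 0.05 is expected where no gene differs. The methods' t-test also called 0 in each. Single-diet genotype comparisons called 0 genes under chow (1687 at an unadjusted p under 0.05, 1 by the methods' t-test) and 0 under HFD (1484, and 0 by the methods' t-test). Pparg differed by 0.15 ± 0.22 (adjusted p = 0.852) and 0.22 ± 0.22 (adjusted p = 0.79). Over both diets 8 genes were higher and 11 lower in arrays labelled Ala/Ala, and with each array's median set to 0 there were 12 higher and 7 lower. At an unadjusted p under 0.05 lay 2510 genes (15.1%), against 5.84% in fat and 7.41% in muscle for genotype over both diets. Genes vary together, so a larger share alone does not show a difference. Tbrg4, a mitochondrial RNA-binding protein, was higher by 0.37 ± 0.06 (adjusted p = 0.00573), Lmnb2, a nuclear lamin, by 0.28 ± 0.06 and the translation factor Denr by 0.26 ± 0.05. Hoxb5os fell by 0.33 ± 0.06, Pwwp2b by 0.29 ± 0.06 and the myosin Myo19 by 0.25 ± 0.05, and Pparg differed by 0.19 ± 0.16 (adjusted p = 0.576). Of 40 single omissions 31 moved this count by over 1.5 times, from 2 without Mouse105 to 36 without Mouse77. With mouse number as a covariate it was 1, and of the genes named here only Tbrg4 passed. The diet-by-genotype test called 0 genes, with 610 at an unadjusted p under 0.05.

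The cholesterol synthesis list was 0.42 higher in liver arrays labelled Ala/Ala HFD than Ala/Ala chow (adjusted p = 3.33e-26, and 0.0354 with an estimated correlation). Of 19 members 0 passed over all genes and 13 rose adjusted over the list alone. In Pro/Pro the difference was not called. In the same comparison the lipogenesis list was 0.19 higher (adjusted p = 1.57e-07, and 0.261 with an estimated correlation), the fatty acid oxidation list differed by -0.10 (adjusted p = 1.94e-06, and 0.497 with an estimated correlation), the PPARα target list by -0.16 (adjusted p = 0.00406, and 0.534 with an estimated correlation), the unfolded protein response list by 0.08 (adjusted p = 0.0323, and 0.603 with an estimated correlation) and the macrophage list by 0.11 (adjusted p = 0.0474, and 0.603 with an estimated correlation). The macrophage call ended with each array's median set to 0 and in 11 of 20 single omissions, with means of 0.05 without Mouse77 and 0.07 without Mouse80. The PPARα call ended without Mouse77 (-0.11), and that of the unfolded protein response in 7 of 20 omissions, with means of 0.04 without Mouse77, 0.03 without Mouse80 and 0.12 without Mouse128.

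Between arrays labelled HFD and chow in Pro/Pro 3 lists were called. Lipogenesis differed by -0.12 (adjusted p = 0.0192), macrophage markers by -0.16 (adjusted p = 0.0415) and interferon response by -0.16 (adjusted p = 0.00384), each with an adjusted p of 0.649 with an estimated correlation. Of 20 single omissions 6, 11 and 3 ended these calls, with means of -0.07 for lipogenesis without Mouse110, and of -0.10 for macrophage markers and -0.10 for interferon response without Mouse141. The macrophage call also ended with each array's median set to 0.

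By genotype label, cholesterol synthesis differed by -0.17 on chow (adjusted p = 0.0122, and 0.704 with an estimated correlation) and by 0.23 on HFD (adjusted p = 5.6e-05, and 0.855 with an estimated correlation), and lipogenesis by -0.19 on chow (adjusted p = 0.000401, and 0.568 with an estimated correlation) and 0.13 on HFD (adjusted p = 0.0252, and 0.855 with an estimated correlation). The lipogenesis call on HFD ended in 7 of 20 omissions, to 0.07 without Mouse110, and with each array's median set to 0 or probe sets averaged. The chow call of cholesterol synthesis ended in 4 of 20. On chow extracellular matrix genes differed by -0.24 (adjusted p = 1.39e-06), macrophage markers by -0.22 (adjusted p = 0.00242), immediate early genes, a sign of sample quality, by -0.21 (adjusted p = 0.019), fatty acid oxidation by 0.09 (adjusted p = 0.00153), bile acid synthesis by 0.13 (adjusted p = 0.0117) and xenobiotic metabolism by 0.21 (adjusted p = 0.0255), each with an adjusted p of 0.568 with an estimated correlation. The immediate early call ended in 4 of 20 omissions and the xenobiotic call in 7. Oxidative phosphorylation was 0.04 higher on HFD (adjusted p = 0.0252, and 0.855 with an estimated correlation) and 0.03 over both diets (adjusted p = 0.038, and 0.9 with an estimated correlation), calls that 7 of 20 and 16 of 40 omissions ended, and extracellular matrix genes differed by -0.16 over both diets (adjusted p = 0.000142, and 0.9 with an estimated correlation). The tests of the difference between diets are given further on, and no liver list other than cholesterol synthesis by diet in Ala/Ala kept its call with an estimated correlation.

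A knock-in mouse can carry chromosome of the donor strain around the edited gene, so the place of the genotype calls was tested. Within 100 annotated genes on each side of Pparg on chromosome 6 (gene order of GRCm38.p6) lay 1 of the 9 fat calls, with 0.0439 expected (two-sided Fisher's exact test, p = 0.0431), which rests on Tmcc1 alone, and 2 of the 6 muscle calls, with 0.0293 expected (p = 0.000348). In liver 0 of 19 lay there (p = 1). With 200 genes on each side 6 of 9 fat calls (p = 3.02e-11), 5 of 6 muscle calls (p = 2.63e-10) and 0 of 19 liver calls (p = 1) lay within. With 50 genes on each side 1 fat call (p = 0.0231) and 0 muscle calls did. In gene order from Pparg, Tmcc1 was at 23, Zfp9 at 80, Erc1 at 100, Hdhd5 at 115, Bid at 124, Slc6a13 at 136 and Apobec1 at 162. Hdhd5 and Bcl2l13 were called in fat and muscle with the same sign. The tissues share 31 mice, so these calls are not independent, and the other probe sets of Bcl2l13 differed in the opposite direction in both.

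**Figure D2:**
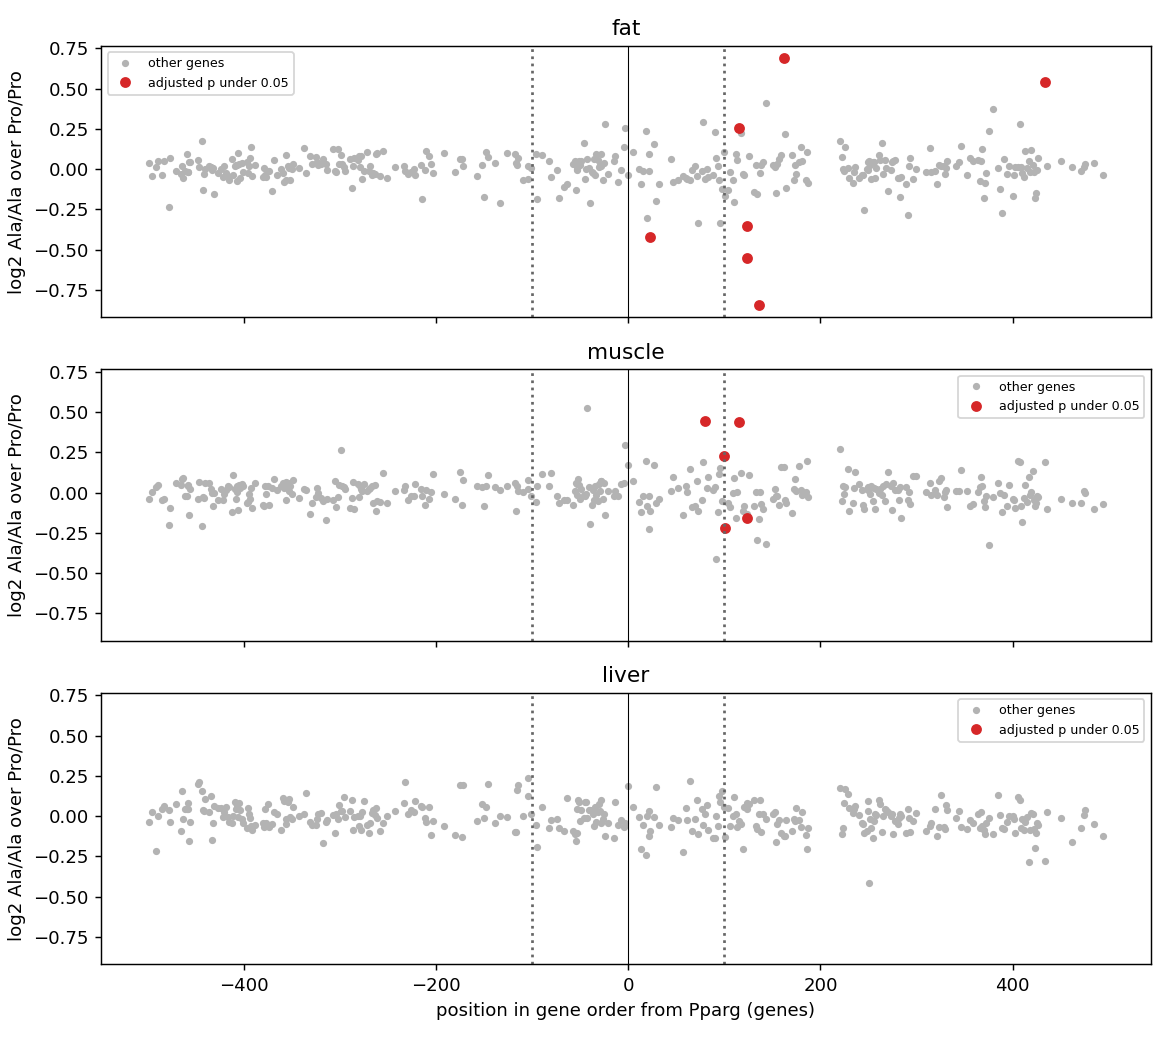
Log2 ratio of Ala/Ala over Pro/Pro over both diets (vertical axis) against position in gene order from Pparg (horizontal axis, genes) in fat, muscle and liver, with called genes in red and dotted lines at 100 genes on each side. Called genes of fat and muscle in this range, such as Hdhd5 at 115 and Slc6a13 at 136, all lie on the right of Pparg, and liver has 0 called genes in it.

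Differences between tissues were tested in a joint fit. Those with liver rest on its labels, which are in doubt, so they are not shown to be more than the effect in fat or muscle. The genotype effect differed between fat and liver for 112 genes, between fat and muscle for 3 and between liver and muscle for 6. For fat and muscle 6 of 100 random splits gave as many. Among these 3 genes Slc6a13 had a fat-minus-muscle difference of -0.681 ± 0.0973 (adjusted p = 4.3e-06, and 4.2e-05 with mouse number as a block). Dtna differed by -0.522 ± 0.0932 (adjusted p = 0.00148, and 0.0071 with the block). Cacna2d4 differed by 0.482 ± 0.0953 (adjusted p = 0.0102) and did not pass with the block (adjusted p = 0.0512). Slc6a13 had a fat-minus-liver difference of -0.86 ± 0.09 (adjusted p = 1.04e-10) and Hdhd5 of 0.29 ± 0.06 (adjusted p = 0.0111). The diet effect differed between fat and liver for 4622 genes, between fat and muscle for 4365 and between liver and muscle for 209. Mmp9 had a fat-minus-liver diet difference of -1.99 ± 0.09. With each array's median set to 0, 58 of 133 fat-minus-liver genotype differences were positive, against 65 of 112, and 2 of 7 liver-minus-muscle differences, against 1 of 6. With mouse number as a block 47 of 100 fat-minus-liver genotype differences were positive.

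Arrays with the same mouse number were compared across tissues. On 52 genes whose deviations from the group means correlated above 0.65 between fat and muscle, the array of the same number was the best match for 30 of 31 mice from fat to muscle, with a mean correlation across genes of 0.701. From fat to liver it was the best match for 1 of 36 mice (mean -0.0426) and from muscle to liver for 1 of 35 (mean -0.0276). The 52 genes were chosen for their correlation between same-numbered fat and muscle arrays, so the fat to muscle match was in part built in. The matches to liver were scored on genes not chosen for them, so the 2 kinds of match are not on equal terms. Over all genes the same-number medians were 0.0273 for fat and muscle, -0.00523 for fat and liver and -0.00379 for muscle and liver. Genes are not independent replicates.

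**Figure D3:**
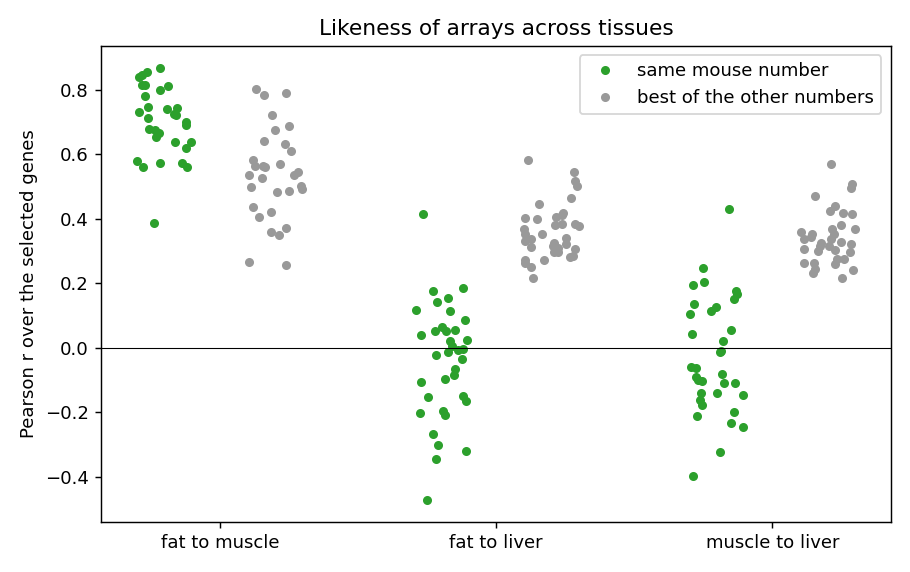
Pearson correlation over 52 genes chosen on fat and muscle (vertical axis) between arrays of different tissues, for the same mouse number (green) and for the best of the other numbers (grey), a point per mouse. From fat to muscle the same number averaged 0.701, and from fat to liver -0.0426.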

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

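The tests of mouse matching, of noise in the liver and of the place of the genotype calls were read after those results had been seen, although the window around Pparg was set before, and the other tests named here were written down before their results.

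The liver arrays showed no diet calls and no likeness to same-numbered arrays of fat and muscle. Noise alone is argued against, since the cholesterol synthesis genes had a median pairwise correlation of 0.665 over liver arrays within groups. Whether liver lacks the variation that fat and muscle share cannot be told, since the best liver match of any number averaged 0.364, below the 0.537 of other mice from fat to muscle but above 2 references tried earlier, 0.332 and 0.335. The reference of 0.537, the third tried, was raised by choosing the genes on fat and muscle, and the earlier ones broke the correlation between genes. The median SD of these 52 genes over the arrays of a tissue was 0.26 in liver, 0.302 in fat and 0.292 in muscle. An SD does not show whether the variation is shared. Wrong labels on liver arrays stay open, since 10 chromosome 6 genes called by genotype in fat or muscle had a mean signed correlation of 0.196 over liver arrays, above 0.057, the 95th percentile of random gene sets, but differed by -0.03 between the liver genotype labels, and the correlations in fat (0.257) and muscle (0.384), where these genes were chosen, are no fair reference.

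Genotype calls in fat and muscle lay near Pparg. A strain variant around the edited gene may account for these calls, with odds ratios of 25.8 in fat and 104 in muscle. These rest on 1 and 2 calls within the window. Within 50 genes on each side muscle had 0, with 0.0155 expected. A sequence variant under a single probe set stays open. Of 12 calls on the chromosome 5 had other probe sets, and 3 of these had at least 1 that differed the same way at an unadjusted p under 0.05 in limma. For Tmcc1 in fat that probe set gave -0.149, while its others gave 0.00912, 0.0416 and 0.0728. For Erc1 in muscle the values were 0.159 and 0.000279. The calls without such a probe set were Bcl2l13 in fat and in muscle. The sequence flanking the edited gene was not measured here, so effects of the amino acid change and of any flanking variant were not separated.

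The fatty acid oxidation list was higher on HFD in muscle. In Ala/Ala, with the adipocyte list as a covariate chosen after seeing the data, the mean difference was 0.317, against 0.318 without it. This argues against adipocytes in those samples as its cause. In Pro/Pro the mean difference was 0.24 with and without the covariate. There the adipocyte list averaged -0.04 on chow and 0.01 on HFD. A covariate so alike on both diets could hardly change the value, so the Pro/Pro test cannot decide. A response to the diet remains a hypothesis, and no other technical explanation was tested.

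Random splits of the mice, 100 with the real one, were used to ask whether chance gives as many calls. In fat the numbers of splits with as many calls were 2 for genotype on chow (3 genes, highest other 5), 2 on HFD (17, highest other 100), 1 over both diets (9, highest other 1), 1 for diet in Pro/Pro (3991, highest other 745), 1 in Ala/Ala (4564, highest other 594) and 100 for the interaction (0, highest other 220). In muscle they were 1 for chow (5, highest other 1), 1 for HFD (2, highest other 1), 1 for both (6, highest other 1), 1 for diet in Pro/Pro (295, highest other 12), 1 in Ala/Ala (457, highest other 2) and 100 for the interaction (0, highest other 1). In liver they were 100 for chow (0, highest other 3), 100 for HFD (0, highest other 22), 2 for both (19, highest other 22), 100 for diet in Pro/Pro (0, highest other 20), 100 in Ala/Ala (0, highest other 1) and 100 for the interaction (0, highest other 87). Between tissues they were 3 for genotype in fat and liver (112, highest other about 1.5e+02), 6 in fat and muscle (3, highest other 1015), 1 in liver and muscle (6, highest other 2), 1 for diet in fat and liver (4622, highest other 859), 1 in fat and muscle (4365, highest other 275) and 2 in liver and muscle (209, highest other 286). Fewer than 5 splits reached the count except for the genotype difference between fat and muscle and for the counts of 0. Chance is not excluded by this, since only 100 splits were used per count, without adjustment for the number of counts. In some of these comparisons a random split called more genes than the real one. These were genotype on chow and HFD in fat, over both diets in liver and between fat and liver, and diet between liver and muscle. Those with liver rest on its doubted labels. Why some splits gave several times the real count was not tested.

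Single arrays stood apart from their group in 14 of 384 groups of values, where chance gives about 1 in 20. On list means these were interferon response at 0.76 in fat Pro/Pro chow Mouse106 and 0.54 in muscle Ala/Ala HFD Mouse117, immediate early genes at 0.5 in liver Pro/Pro HFD Mouse147, macrophage at 0.66 in fat Ala/Ala chow Mouse109, lymphocyte at 0.13 in muscle Pro/Pro chow Mouse141, mesothelium at -0.79 in fat Pro/Pro HFD Mouse131, slow myofibre at -1.06 in muscle Pro/Pro HFD Mouse125 and fast myofibre at 0.10 in muscle Pro/Pro chow Mouse84. On genes they were Apobec1 at 1.38 in fat Ala/Ala chow Mouse109, Tmcc1 at -0.36 in fat Ala/Ala chow Mouse155, Zfp9 at 0.41 in muscle Pro/Pro chow Mouse105, Arf3 at 0.20 in liver Pro/Pro HFD Mouse131 and -0.0272 in liver Ala/Ala HFD Mouse149, and Dlx2 at 0.40 in liver Pro/Pro chow Mouse105.

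The diet effect of some lists differed between genotypes by the set test of the interaction, and none kept this with an estimated correlation. In fat the mean differences were -0.10 for insulin signalling, 0.12 for interferon response and -0.17 for immediate early genes. Interferon response fell to 0.03 without Mouse106 and immediate early genes to -0.11 without Mouse109, and the calls of insulin signalling, interferon response and immediate early genes ended in 16, 15 and 4 of 37 single omissions. In muscle they were 0.25 for PPARα targets, 0.078 for fatty acid oxidation, 0.32 for slow myofibre and 0.53 for adipocyte genes. Slow myofibre was 0.19 and not called without Mouse125, and with the adipocyte list as a covariate it was 0.48 and PPARα targets were 0.15 and not called. In liver they were 0.31 for lipogenesis, 0.40 for cholesterol synthesis, -0.12 for fatty acid oxidation, 0.16 for extracellular matrix, 0.12 for interferon response, -0.12 for bile acid synthesis, -0.25 for xenobiotic metabolism and 0.26 for macrophage genes. Of 40 single omissions 20 ended the call of interferon response (0.06 without Mouse141, 0.07 without Mouse91), which also ended with each array's median set to 0, 10 that of bile acid synthesis, 4 that of xenobiotic metabolism and 1 that of extracellular matrix. Tests between tissues, which for liver rest on its doubted labels, gave 112, 3 and 6 genes for genotype and 4622, 4365 and 209 for diet. Among 7132 unnamed probe sets, genotype calls over both diets numbered 2 in fat, 1 in muscle and 1 in liver. No comparison of genes used these probe sets, but the setting with every probe set on its own did.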

How the results depend on the processing

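The first component of the residuals, the fat arrays left out, the adipocyte covariate, the whole chromosome window and the list tests without single arrays were chosen after seeing the data. Counts are genes unless stated. With every probe set on its own they are probe sets out of 32640, which are not on the same scale as counts of 16643 genes. The cause of a shift was not tested, and signal over background, which could limit these values, is unknown here. Of values for named genes under the other settings 530 kept their direction and side of the threshold, 40 lost the call, 1 gained it and 1 turned (Bcl2l13 in muscle over both diets, to 0.00422 with the mean of all probe sets).

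In fat, quantile normalization gave 0 genotype calls on chow and 11 on HFD. The mean of all probe sets gave 5 on HFD and 5 over both diets. Every probe set on its own, with more tests and counted in probe sets, gave 5 on chow, 14 over both diets, and 7338 and 8781 for diet in Pro/Pro and Ala/Ala. A false discovery rate of 0.20, looser by construction, gave 51 on HFD, 14 over both diets, 6356 and 7698 for diet and 1 for the interaction. Mouse number as a covariate gave 1 for the interaction. The methods' t-test gave 1 on chow and 2 on HFD, and at 0.20 gave 1 on chow and 6372 and 7176 for diet. The first component of the residuals gave 375 on HFD and 230 over both diets, but it is uncorrelated with the groups by construction, so it only shrinks the spread and its p-values are too small. Without arrays with transcripts of other organs, most of them HFD arrays, there were 1 on HFD and 2962 for diet in Ala/Ala.

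In muscle, quantile normalization gave 1 genotype call on HFD and 189 for diet in Pro/Pro. The mean of all probe sets gave 3 on chow and 5 on HFD, and every probe set on its own 5 on HFD and 11 over both diets. Genes above the median variance, with fewer tests, gave 2 on chow, 4 on HFD, 3 over both diets and 157 for diet in Pro/Pro. A false discovery rate of 0.20 gave 16 on HFD and 1053 and 1207 for diet. Mouse number as a covariate gave 66 higher and 81 lower genes for diet in Pro/Pro, about 1.5e+02 in all. The methods' t-test gave 0 on chow, 1 on HFD and 139 for diet in Pro/Pro, and at 0.20 gave 18 on HFD and 934 and 1177 for diet. The adipocyte list as a covariate gave 0 on HFD.

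In liver, genotype calls over both diets were 6 after quantile normalization, 5 with every probe set on its own, 2 among genes above the median variance, 1 with mouse number as a covariate, 1001 at a false discovery rate of 0.20 and 146 with the first component of the residuals. At 0.20 there were 1 on chow, 7 on HFD and 1 for diet in Ala/Ala. The methods' t-test gave 1 on chow, and at 0.20 gave 7 on chow and 1 on HFD. The first component gave 41 on chow, 1 on HFD and 1 for the interaction.

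For tissue differences at 0.20, genotype gave 1179, 5 and 12 for fat and liver, fat and muscle, and liver and muscle, and diet gave 7230, 6695 and 528. With mouse number as a replicate block, which rests on the labels giving the same number to the same animal and was not borne out for liver, where the own number was the best match for 1 of 36 mice from fat and 1 of 35 from muscle, the genotype counts at 0.05 were 100, 2 and 5 and the diet counts 4420, 4010 and 187, none moved by over 1.5 times. For fat and liver the block turned the split by genotype from 65 higher and 47 lower to 47 higher and 53 lower. Within 50 genes on each side of Pparg there were 0 muscle calls, with 0.0155 expected (Fisher's exact test, p = 1). So few expected calls cannot show a lack of them, and 2 lay within 100. With 200 there were 6 fat and 5 muscle calls. At 0.20 the calls within 100 were 3 of 14 in fat (0.0683 expected), 3 of 8 in muscle (0.039 expected) and 5 of 997 in liver (4.86 expected, p = 0.816). On the whole chromosome lay 7 of 9 fat calls, 5 of 6 muscle calls and 1 of 19 liver calls. Shared diet calls at 0.20 were 2416 higher and 2349 lower in fat and 171 and 276 in muscle. With an estimated correlation 0 of 23 list tests held in fat, 3 of 25 in muscle and 1 of 30 in liver.

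With each mouse left out, fat genotype counts ran from 2 to 3 on chow, 3 to 25 on HFD and 7 to 11 over both diets, and fat diet counts from 3658 to 4008 in Pro/Pro and 3871 to 4878 in Ala/Ala. On HFD the count was 3 without Mouse110, Mouse111 or Mouse149, 4 without Mouse99, 5 without Mouse80, Mouse95, Mouse137 or Mouse152, 6 without Mouse131, 8 without Mouse143 and 9 without Mouse117. Muscle genotype counts ran from 2 to 6 on chow (2 without Mouse73, 3 without Mouse101 or Mouse106), 1 to 6 on HFD (6 without Mouse127, 5 without Mouse128, 1 without Mouse80, Mouse94, Mouse99, Mouse117, Mouse118, Mouse137, Mouse149 or Mouse152) and 6 to 11 over both diets (11 without Mouse84, 10 without Mouse127). Muscle diet counts ran from 193 to 305 in Pro/Pro (193 without Mouse94 or Mouse147, 195 without Mouse91, 196 without Mouse106) and from 333 to 476 in Ala/Ala. Liver genotype counts ran from 0 to 2 on chow (2 without Mouse109, 1 without Mouse155), 0 to 0 on HFD and 2 to 36 over both diets, where 31 of 40 omissions moved the count by over 1.5 times. Liver diet counts ran from 0 to 0 in Pro/Pro and 0 to 1 in Ala/Ala (1 without Mouse119 or Mouse128).

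List tests without single arrays turned the direction in 1 of the lists given, PPARα targets by diet in Pro/Pro muscle (0.0542), which ran from -0.00643 without Mouse105 to 0.0981 without Mouse84 and lost its call in 4 of 16 omissions. The cholesterol synthesis list by diet in fat and in liver arrays labelled Ala/Ala, the fatty acid oxidation list by diet in muscle and the adipocyte list by genotype in muscle on HFD lost their call in 0 omissions.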
